A study of Mus musculus with 36 samples.

How the data were processed

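Liver RNA of C57BL/6 mice was sequenced in 4 groups of 3 libraries each: doxycycline-treated controls of wild type genotype, mice with a doxycycline-inducible YAP transgene (YAP Tg), YAP transgenic mice that lack Tet1 per the labels (Tet1 KO YAP Tg), and Tet1 KO YAP Tg mice that were also given decitabine. YAP is the transcriptional co-activator that the Hippo pathway restrains, TET1 oxidises 5-methylcytosine, and decitabine is a cytidine analogue that traps DNA methyltransferases. Per the labels, doxycycline was given at 50 mg/L in drinking water and decitabine at 0.5 mg/kg a day by injection for 10 days, and RNA was extracted with TRIzol and treated with DNase. The labels do not say from which species the transgenic YAP comes, which part of Tet1 is deleted, or whether the 3 libraries of a group come from separate animals. The series also lists 24 of its 36 samples under assays of methylated DNA, of TEAD4 and TET1 binding and of input DNA, and these are not analysed here because no table of values for them was at hand. There was no group with the Tet1 deletion but no transgene, and no control group given decitabine.

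The authors aligned reads to mm10 and counted and compared genes with TopHat2, featureCounts and edgeR, per the submitters' processing notes, which give no versions, no order and no options. Bowtie2, MACS2 and Picard are named there too, for the other assays. The table holds 18591 genes by symbol. Its columns are in different units. For the control, YAP Tg and Tet1 KO YAP Tg libraries, the deposited values are a normalised signal. Every non-zero value in these 9 columns passed as a whole multiple of the value of 1 read. The tolerance was 0.02 of a read at low counts and grew with the count at high ones, where the largest values could not fail. The columns sum to between 846970 and 1184330, which is the range of RPM values after scaling with TMM factors. Levels on this scale are called normalised reads below. For the 3 decitabine libraries, the deposited values are TPM, in which reads are divided by gene length, and these columns sum to between 999722 and 999852. The same table holds the authors' own comparisons: log2 fold changes and mean log2 expression per the file headers, a likelihood ratio score per the file headers, and p-values with their false discovery rates per the file headers. These statistics by the authors were used only to set the deposited fold changes beside the ones computed here.

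Reads were recovered from both units. In the 9 scaled libraries 100% of non-zero values gave whole reads within the tolerance given above. In the decitabine libraries the ratios between the 3 values of a gene gave whole reads and a whole-number gene length for 17096 of 17105 genes (99.9474%), and the other 9 were left out of comparisons with decitabine. Tested on simulated data of known reads and lengths, 92.26% of genes with a mean of at least 10 reads came back exactly. Another 7.742% came back with reads too small by a whole factor. Of all genes at that depth, 5.876% were too small by a factor of 2, 1.2% by 3 and 0.6659% by more. The recovered depth was 19986112, 25067861 and 19954131 reads in the controls, 23528750, 24765820 and 23468633 in YAP Tg, 22766044, 22347119 and 19082417 in Tet1 KO YAP Tg, and 25781503, 31714075 and 20682026 in the decitabine libraries. These are reads, not molecules, so intervals and floors given for low counts cover counting error only.

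The plan had been edgeR's quasi-likelihood test on counts. Since the table holds no counts, that plan was replaced by limma on log2(value + 0.5) with an intensity trend in the variance, and edgeR on recovered reads became an alternative, which called 8073 genes in YAP Tg against control, 7511 in Tet1 KO YAP Tg against YAP Tg and 8478 in decitabine-treated against untreated Tet1 KO YAP Tg. Fold changes are on the log2(value + 0.5) scale, which understates changes of genes with few reads. Comparisons among control, YAP Tg and Tet1 KO YAP Tg used the deposited values of these 9 libraries in one fit, so that the groups share one estimate of the spread. Comparisons with decitabine used all 12 libraries, with the recovered decitabine reads brought to the same scale of normalised reads by TMM factors. Genes were kept with a value of at least 0.5 in at least 3 libraries, which left 13730 genes without and 13940 with the decitabine libraries. All tests are two-sided and p-values are adjusted by Benjamini and Hochberg; a gene is called changed at an adjusted p below 0.05. Where decitabine libraries enter, treatment and processing cannot be told apart for a single gene or list, since no other library shares their unit.

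Gene lists for pathways and cell types, 35 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over the lists of a comparison. Of these lists, 32 had at least 5 measured members; pancreas, adipose and gut genes, germline genes and mitochondrially encoded genes had fewer and were not tested. Some lists share members, so they are not separate evidence. Examples are Lcn2 (neutrophil and acute phase), Cyp2e1 (cytochrome P450 and pericentral), Cyp7b1 (bile acid and male-biased) and H19 (oncofetal and imprinted). Member counts are given over all genes tested and adjusted over the list alone. The genes named in the text follow a rule: Yap1, Tet1, Tet2, Tet3, Cyr61, Ctgf, Ankrd1 and Afp always; the 6 largest rises and 6 largest falls among called genes whose groups do not overlap, with a mean of at least 5 in the higher group and leaving out symbols of unnamed transcripts; up to 3 called members of each list with the largest change, or up to 2 with the highest mean where none was called; and 8 genes for the pattern of 3 calls. Not every gene that the rule selects is named. The comparisons, the lists, this rule and a first set of alternative choices were made before the data were examined. Genes outside the rule are named as chosen after their values were seen.

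Overlaps between comparisons that share libraries were set beside 50 simulations in which no group differs and beside the overlap of independent lists (the product of both counts over the genes tested). The analysis was tested on simulated data with 200 changed genes among 14210 in each of 10 simulations. For YAP Tg against control it recovered 21.6% of changes of 1.5-fold, 68.5% of 2-fold and 90.9% of 4-fold, and 6.23% of all calls were false. For Tet1 KO YAP Tg against YAP Tg the shares were 19.7%, 65.5% and 89.8%, with 5.06% of calls false. For decitabine-treated against untreated Tet1 KO YAP Tg they were 20.1%, 70.1% and 92.4%, with 5.59% false. All groups were simulated with a spread estimated over all 12 libraries, decitabine included. The real libraries without decitabine vary less, so these shares need not hold for the comparisons among them.

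Alternative choices fixed at that stage were DESeq2 size factors, no filter and a stricter filter of a mean of at least 1, only the 6 libraries compared, the replicate number as a block, DESeq2's Wald test, an added 2-fold limit and leaving out each library in turn. After the data were seen, the following were added: edgeR on recovered reads; pseudocounts of 0.1 and 2; near-identical libraries added together; decitabine TPM values as deposited; decitabine reads doubled before a gene counts as lower; all 12 libraries in every fit; and leaving out genes with a named pseudogene. Symbols were matched to the GRCm38.p6 reference tables (the assembly that mm10 stands for), in which 17759 symbols (95.5%) were found, and 753 more as older names. Coordinates are from these tables. The notes do not say whether reads were counted by strand, so reads of overlapping or antisense genes cannot be separated. R 4.3.3 was used with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and data.table (1.17.8), and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.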

Results

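Liver RNA was measured in 12 libraries, 3 each from doxycycline-treated control mice, mice expressing the YAP transgene, YAP transgenic mice that per the labels lack Tet1, and such mice that had received decitabine. YAP is a co-activator that works through TEAD transcription factors, and TET1 is an enzyme of DNA demethylation. The recovered depth lay between 19082417 and 31714075 reads per library, and group means below are normalised reads ± SD with n = 3. Tet1 itself was at 0.682 ± 0.296 in controls, 9.15 ± 0.673 in YAP Tg, 0.931 ± 0.333 in Tet1 KO YAP Tg and 2.28 ± 1.07 with decitabine. Tet1 lies on chromosome 10, 62804569 to 62880014 (GRCm38.p6, the mm10 assembly, as for all positions below). Its level in Tet1 KO YAP Tg was not called different from that in controls (adjusted p = 0.32), and with decitabine it was higher than in controls (log2 1.20, adjusted p = 0.00145). Its reads therefore do not show the deletion, and "without Tet1" below follows the labels. Reads of the 45S ribosomal RNA precursor (Rn45s, named after its values were seen) were 7.82%, 0.148% and 6.44% of the control libraries and at most 0.669% of any other.

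Some libraries of a group were nearly identical. Beyond read sampling, the coefficient of variation between libraries was 0.0153 to 0.0422 among the YAP Tg libraries, 0.0281 to 0.0369 among the Tet1 KO YAP Tg libraries and 0.0276 between control libraries 1 and 3. It was 0.158 and 0.162 between either of these and control 2, and 0.228 to 0.317 among the decitabine libraries. Nothing in the labels says that replicates are separate animals, so a small p-value may measure technical spread in those groups. Each fit takes 1 spread per gene over its groups, so the wider spread of the decitabine libraries is averaged with narrower ones. Standard errors and p-values of comparisons with decitabine are therefore likely too small. Because of the near-identical libraries, the counts of changed genes are also given with libraries that differ by less than 0.05 added together, which leaves 7 libraries. YAP Tg and Tet1 KO YAP Tg then have 1 library each, and all spread comes from the control and decitabine libraries. Counts and p-values of that fit therefore measure no spread within YAP Tg or Tet1 KO YAP Tg.

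The comparison of YAP Tg with control livers shows which transcripts differ when the transgene is on. The YAP targets Ctgf, Ankrd1 and Cyr61 were higher. Ctgf, a secreted matrix protein and classical YAP target, was at 148 ± 3.86 in YAP Tg and 18.8 ± 5.68 in controls (log2 fold change 2.99, SE 0.17, adjusted p = 1.58e-08). Ankrd1, a muscle ankyrin repeat protein that responds to YAP, was at 64.4 ± 2.22 and 0.431 ± 0.298 (log2 6.17), and Cyr61 at 64.0 ± 2.93 and 5.77 ± 0.731 (log2 3.37). Fetal liver genes were higher too. The heparan sulfate proteoglycan gene Gpc3 rose from 1.72 ± 0.186 to 597 ± 8.12, and Afp, the main plasma protein of the fetal liver, from 1.74 ± 0.633 to 21.8 ± 0.886. Cyp2e1, an ethanol-metabolising P450 of hepatocytes near the central vein, was lower, going from 6892 ± 203 to 83.3 ± 3.7 (log2 -6.36, SE 0.0512, adjusted p = 5.94e-16). Reads of the Yap1 gene were lower as well, at 29.9 ± 2.24 against 54.8 ± 6.7 in controls. Because the species of the transgenic YAP is not given, Yap1 reads cannot be assigned to the mouse's own gene or to the transgene.

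**Figure D1:**
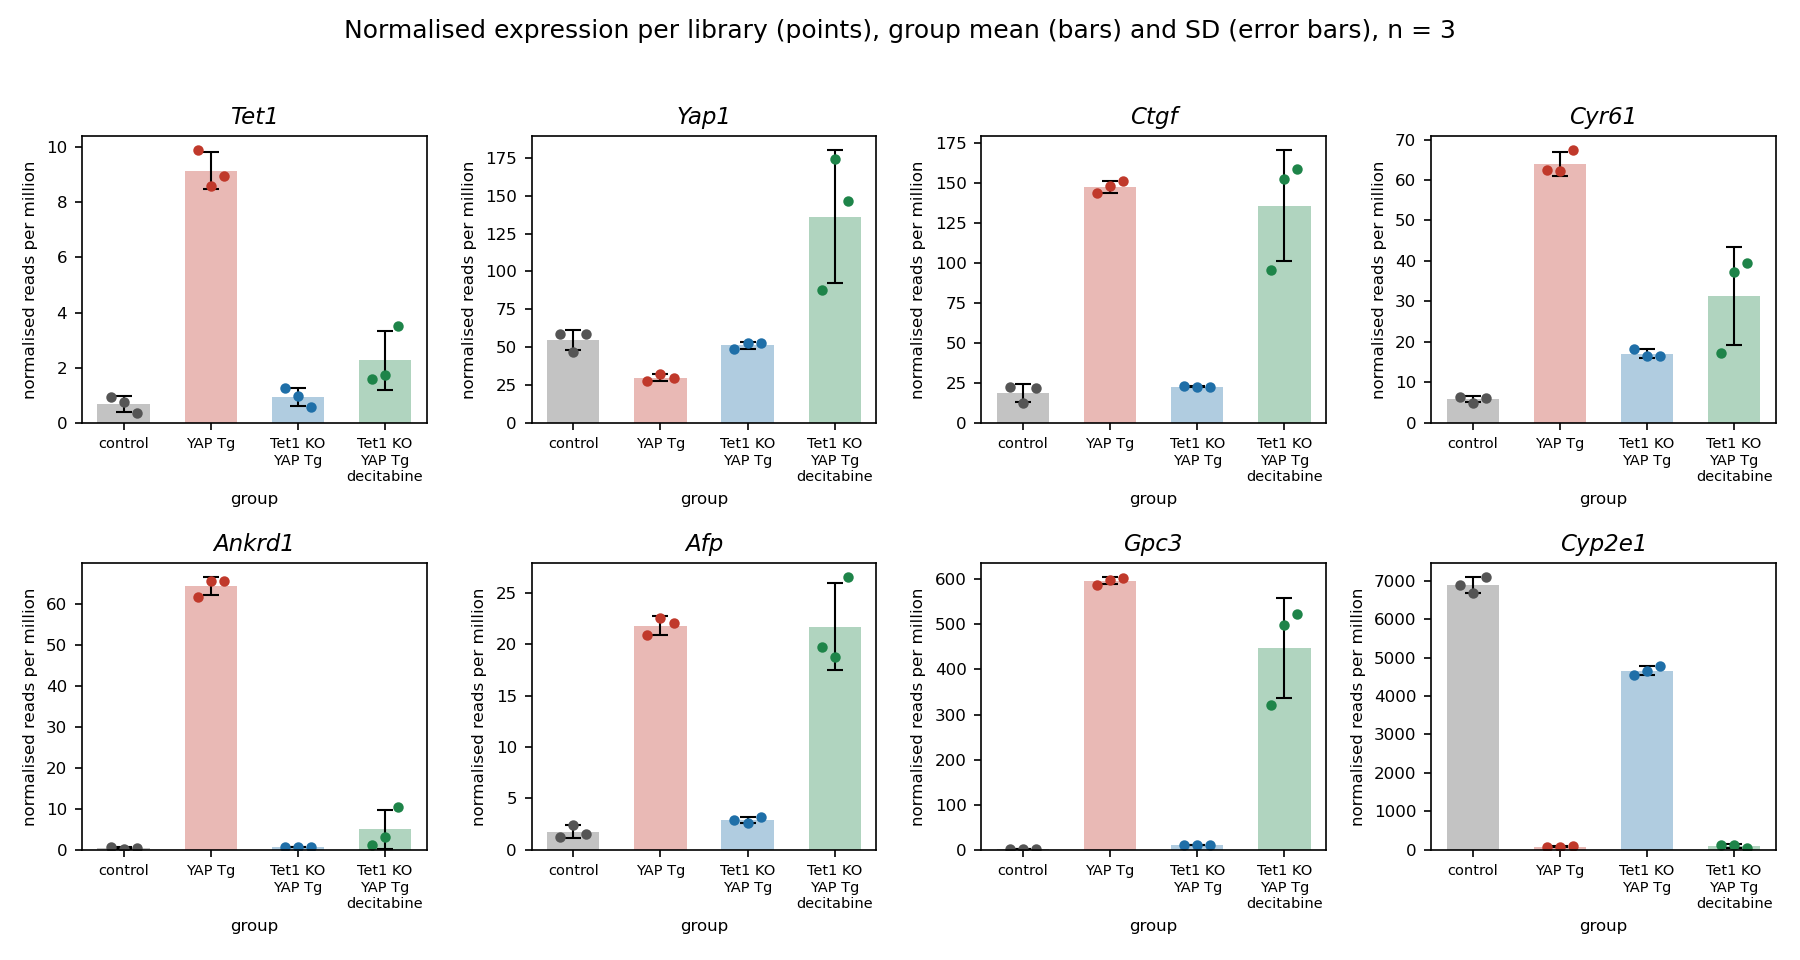
Levels of 8 genes in normalised reads (vertical axes, each starting at 0) in the 4 groups of 3 libraries; points are libraries, bars are means and error bars are SD. Ctgf, Cyr61, Ankrd1, Afp and Gpc3 are higher in YAP Tg than in control and Tet1 KO YAP Tg libraries, and Cyp2e1 is lower.

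Ctgf lies on chromosome 10, 24595441 to 24598682, Cyr61 on chromosome 3, 145646970 to 145649985, Ankrd1 on chromosome 19, 36111964 to 36119844, Afp on chromosome 5, 90490713 to 90508907, Gpc3 on chromosome X, 52272426 to 52613974, Cyp2e1 on chromosome 7, 140763831 to 140774977 and Yap1 on chromosome 9, 7932000 to 8004596. The notes do not say over which exons reads were counted.

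Among the largest rises passing the rule were those of Fgfbp1, Gpc3, Fam83b, Spink3 and Psca. Fgfbp1, which encodes a carrier of fibroblast growth factors, had no read in controls and 243 ± 5.52 normalised reads in YAP Tg, at least 4570-fold higher against a floor of 3 reads over the group. Psca, a surface antigen of prostate stem cells, was likewise without reads in controls and at least 1560-fold higher. Spink3, a trypsin inhibitor, rose from 0.202 ± 0.059 to 131 ± 3.68. The largest falls were those of Elovl3, an elongase of very long fatty acids, and of Mup7, Mup11, Mup2, Mup17 and Mup14, which encode major urinary proteins. Mup7 had 1559 ± 264 normalised reads in controls and 0.0469 ± 0.0407 in YAP Tg. Elovl3, with 1 read over the YAP Tg group, was lower by a factor of 48500 (95% counting interval 8710 to 1920000), and Mup11, with 3 reads, by a factor of 21100 (7230 to 102000). Mup genes are near-identical copies, so the share of reads that each copy received is uncertain.

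Among lists of pathway genes, 16 of 21 YAP/TEAD target genes were higher and 5 lower (median log2 2.03, adjusted p = 0.000797, and adjusted p = 0.202 with an estimated correlation). Besides Ankrd1, the largest rises were those of Gadd45b, a stress-induced growth regulator, from 1.58 to 34.0, and of the LIM protein gene Ajuba, from 3.92 to 65.0. Of the Hippo pathway components, 9 were higher, 5 lower and 5 not called, and the list was not called (adjusted p = 0.318). Tead4, a DNA-binding partner of YAP, rose by 3.55 on the log2 scale and the scaffold gene Wwc1 by 2.14. All 24 mitosis genes were higher (median 2.42, adjusted p = 1.29e-08, and adjusted p = 0.305 with an estimated correlation), among them the kinesin gene Kif20a from 1.89 to 19 and Cdc20, an activator of the anaphase-promoting complex, from 0.853 to 8.97. In the DNA replication list 19 of 23 genes were higher (adjusted p = 9.93e-06, and adjusted p = 0.142 with an estimated correlation), with log2 fold changes of 2.20 for E2f1 and 1.97 for Mcm5. Oncofetal liver genes rose, 12 of 13 (median 2.33, adjusted p = 3.45e-05, 0.0496 with an estimated correlation). Beside Gpc3 these were led by the imprinted transcript H19, from 2.42 to 166 ± 4.53, and the aldo-keto reductase Akr1b7, from 0.25 to 34.6. Cholangiocyte and progenitor markers were higher in 10 of 14 (adjusted p = 0.00287, and adjusted p = 0.16 with an estimated correlation); osteopontin (Spp1) rose from 50.5 ± 5.21 to 1662 ± 15. The p53 target list rose, with 16 of 19 members higher (adjusted p = 0.000257, 0.0479 with an estimated correlation), including the antiproliferative gene Btg2 (log2 3.19, 118 in YAP Tg) and Phlda3 from 0.202 to 6.33.

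The DNA methylation list of 16 enzymes and readers was not called (adjusted p = 0.43), with 7 members higher and 4 lower. Tet1 had its largest rise (log2 3.06, SE 0.211, adjusted p = 8.82e-08). The isocitrate dehydrogenase gene Idh2 rose by 2.03, and Mbd1, which binds methylated DNA, went from 80.6 to 17.4. Tet2 was at 30.7 ± 0.381 against 28.6 ± 2.23 (adjusted p = 0.163) and Tet3 at 26.5 ± 2.04 against 25.7 ± 3.52 (adjusted p = 0.681).

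Liver metabolism genes were lower across most lists. Of the cytochrome P450 genes, 18 of 21 fell (median -3.04, adjusted p = 2.23e-08, 0.0318 with an estimated correlation), with Cyp2c29 going from 2451 ± 344 to 15.7 and Cyp4a14 from 259 ± 132 to 0.236. Pericentral genes that respond to Wnt signals were lower in 13 of 14 (median -3.40, adjusted p = 1.86e-07, 0.0318 with an estimated correlation), including the glutamate transporter Slc1a2 from 229 to 2.82. In bile acid synthesis and transport 15 of 18 fell and 3 rose (adjusted p = 3.37e-06, 0.0318 with an estimated correlation), and the uptake carrier Slc10a1 went from 489 to 15.5. In urea cycle and amino acid catabolism 16 of 17 fell (median -1.90, adjusted p = 2.67e-09, 0.0318 with an estimated correlation), with serine dehydratase (Sds) at -2.80 and the ornithine carrier Slc25a15 at -2.61 on the log2 scale. Cholesterol synthesis fell in 19 of 20 genes (median -1.40, adjusted p = 2.23e-08, 0.0412 with an estimated correlation), with Hmgcs1 going from 1454 to 231. Fatty acid oxidation and ketogenesis fell in 15 of 18 (adjusted p = 1.18e-05, 0.0318 with an estimated correlation). Fatty acid and triglyceride synthesis was lower in 14 of 17 genes (adjusted p = 4.11e-06, and adjusted p = 0.172 with an estimated correlation); Thrsp, a lipogenic regulator, went from 139 to 2.79. Gluconeogenesis and glycogen genes, with 8 of 14 lower and 2 higher, were not called as a list (adjusted p = 0.0571), although G6pc, the last enzyme of glucose release, fell from 1203 to 149.6. Of the secreted proteins of hepatocytes 11 of 19 were lower (adjusted p = 0.00696, and adjusted p = 0.526 with an estimated correlation), with transthyretin (Ttr) going from 4385 to 865 and transferrin (Trf) going the other way, from 13420 to 43950.

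Markers of immune cells differed as well. All 17 markers of Kupffer cells and macrophages were higher (median 2.28, adjusted p = 2e-08, 0.0318 with an estimated correlation), including the integrin Itgam from 1.55 to 25.6 and the chemokine receptor Ccr2 from 2.48 to 24.9. Neutrophil markers rose in 12 of 13 (adjusted p = 2.57e-05, 0.0318 with an estimated correlation). Among them the lipocalin Lcn2, which is also in the acute phase list, went from 2.56 to 33.7. Erythroid genes were lower in 7 of 10 (adjusted p = 0.00624, and adjusted p = 0.337 with an estimated correlation), among them Alas2, the first enzyme of heme synthesis in red cells, from 114 to 8.70. Lymphocyte markers, 9 of 13 higher, were not called as a list (adjusted p = 0.0839), and the lymphocyte gene Cd79b rose by 1.44. Interferon response genes (11 of 21 higher, 4 lower, adjusted p = 0.132) and antigen presentation genes (8 of 16 higher, 5 lower, adjusted p = 0.318) were not called, with Ifit2 at 2.5 and Ciita at 1.80. Endothelial markers (5 higher and 8 lower of 16, adjusted p = 0.536) were not called either. Fibroblast and matrix genes had 5 higher and 7 lower of 19, a median of 0.02, a mean of -0.05 and a test pointing down (adjusted p = 0.797). Lrat, a retinol-esterifying enzyme of stellate cells, fell by 1.64 on the log2 scale.

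Of 13730 genes tested, 4951 were higher and 4731 lower in YAP Tg, 70.5% in all, and 1985 and 1288 of these by at least 2-fold. With near-identical libraries added together, 1642 were higher and 987 lower, and the calls of Yap1 (adjusted p = 0.233) and Trf (adjusted p = 0.105) ended. Adjusted over the list alone, the counts differed for Hippo components (9 higher, 6 lower) and antigen presentation (9 and 5), and were as given for the other lists above.

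Tet1 KO YAP Tg was compared with YAP Tg to see which transcripts differ between transgenic livers that per the labels lack Tet1 and those that do not. The YAP targets Ankrd1, Ctgf and Cyr61 were lower without Tet1. Ankrd1 was at 0.646 ± 0.065 in Tet1 KO YAP Tg against 64.4 ± 2.22 in YAP Tg (log2 -5.82, SE 0.184, adjusted p = 1.05e-10), Ctgf at 22.4 ± 0.316 against 148 ± 3.86 and Cyr61 at 17.1 ± 1.05 against 64.0 ± 2.93. The fetal genes Afp (2.91 ± 0.282), Gpc3 (10.2 ± 0.483) and H19 (0.598 ± 0.142) were lower as well. Cyp2e1 was higher, at 4662 ± 116 against 83.3 ± 3.7 (log2 5.80, SE 0.0512, adjusted p = 1.37e-15), and Yap1 reads were at 51.1 ± 2.29 against 29.9 ± 2.24. Tet1 fell by 2.78 on the log2 scale (SE 0.211, adjusted p = 2.46e-07), while Tet2 was at 28.1 ± 0.371 (adjusted p = 0.0994) and Tet3 at 22.7 ± 1.51 (adjusted p = 0.0751).

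Among the largest falls were those of Fgfbp1, with 3 reads over the Tet1 KO YAP Tg group and a level lower by a factor of 5110 (95% counting interval 1750 to 24800), Psca, H19, the potassium channel gene Kcnh7 and the TEAD cofactor gene Vgll3. Vgll3 was at 0.168 ± 0.0993 against 39.9 ± 1.79. The largest rises were all in Mup genes (Mup11, Mup17, Mup2, Mup15, Mup7 and Mup19). Mup7 was at 348 ± 15.2 against 0.0469 ± 0.0407, and Mup19 had no read in YAP Tg and was at least 7380-fold higher without Tet1.

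Of the YAP/TEAD target genes 14 of 21 were lower and 4 higher (median -1.26, adjusted p = 0.00123, and adjusted p = 0.196 with an estimated correlation). Hippo components (9 lower, 5 higher of 19, adjusted p = 0.191) and DNA methylation genes (7 lower, 2 higher of 16, adjusted p = 0.106) were not called; Tead4 fell from 11 to 0.634. All 24 mitosis genes were lower (median -1.79, adjusted p = 6.08e-08, and adjusted p = 0.302 with an estimated correlation), with the centromere protein gene Cenpf going from 34.2 to 7.66. DNA replication genes were lower in 17 of 23 (adjusted p = 0.000103, and adjusted p = 0.159 with an estimated correlation), including the helicase gene Mcm6 at -1.48. Oncofetal genes were lower in 11 of 13 (median -2.31, adjusted p = 3.86e-05, and adjusted p = 0.0554 with an estimated correlation). Cholangiocyte and progenitor markers were lower in 8 and higher in 4 of 14 (adjusted p = 0.0229, and adjusted p = 0.239 with an estimated correlation), with the progenitor marker Prom1 going from 25 to 2.09. The p53 targets fell in 17 of 19 (adjusted p = 5.27e-06, 0.0313 with an estimated correlation), with Btg2 at 17.8 against 118.

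Liver metabolism genes were higher without Tet1. All 17 genes of urea cycle and amino acid catabolism rose (median 1.73, adjusted p = 1.34e-10, 0.0313 with an estimated correlation), with argininosuccinate synthase (Ass1) going from 397 to 1948. The lists of cytochrome P450 (16 of 21 higher, 3 lower, adjusted p = 4.05e-06, 0.0333 with an estimated correlation), bile acid synthesis and transport (16 of 18, 5.89e-08, 0.0313), cholesterol synthesis (18 of 20, 6.22e-09, 0.0333) and pericentral genes (13 of 14, 6.08e-08, 0.0313) also rose. Cyp2c29 went from 15.7 to 1252, Slc10a1 from 15.5 to 456, Fdps, which makes farnesyl diphosphate, from 44.5 to 338, and Cyp1a2 from 13 to 310.5. Fatty acid and triglyceride synthesis was higher in 16 of 17 (median 1.69, adjusted p = 8.63e-09, and adjusted p = 0.0957 with an estimated correlation), with Thrsp rising from 2.79 to 701 ± 13. Fatty acid oxidation and ketogenesis was higher in 13 and lower in 3 of 18 (adjusted p = 0.00298, and adjusted p = 0.0867 with an estimated correlation), with the nuclear receptor Ppara at 1.53. Gluconeogenesis and glycogen genes were higher in 11 of 14 (adjusted p = 0.000987, and adjusted p = 0.122 with an estimated correlation), including the glycogen phosphorylase Pygl at 1.64. Secreted proteins of hepatocytes (12 higher, 5 lower of 19) were not called (adjusted p = 0.0673), with coagulation factor IX (F9) rising from 124 to 362.

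Immune markers were lower. Kupffer cell and macrophage markers fell in 16 of 17 (median -1.99, adjusted p = 1.19e-08, 0.0313 with an estimated correlation) and neutrophil markers in all 13 (median -2.12, adjusted p = 5.27e-06, 0.0313 with an estimated correlation). Lysozyme (Lyz2) went from 381 ± 3.12 to 53.8 ± 3.57 and the protease gene Mmp9 from 5.83 to 0.330. Lymphocyte markers were lower in 6 of 13 (adjusted p = 0.0408, and adjusted p = 0.454 with an estimated correlation), a call that ended in 5 of the 6 fits that left out a library of YAP Tg or Tet1 KO YAP Tg (adjusted p = 0.0511 to 0.0736). Erythroid genes were higher in 7 of 10 (adjusted p = 0.0189, and adjusted p = 0.392 with an estimated correlation), with Alas2 at 113. Interferon (6 higher, 11 lower, adjusted p = 0.382), fibroblast (9 and 4, 0.233) and endothelial genes (7 and 4, 0.566) were not called. Antigen presentation genes were 7 higher and 6 lower, with a median of 0.09, a mean of -0.40 and a test pointing down (adjusted p = 0.889); H2-Ab1, a class II chain, fell by 2.05 on the log2 scale.

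Without Tet1, 4587 genes were higher and 4664 lower than in YAP Tg (67.4% of 13730), 1116 and 1714 of them by at least 2-fold. With near-identical libraries added together 527 were higher and 744 lower, and the calls of Yap1 (adjusted p = 0.388), Cyr61 (adjusted p = 0.0711) and Mcm6 (adjusted p = 0.0626) ended. Adjusted over the list alone, counts differed for DNA replication (18 lower), fatty acid and triglyceride synthesis (16 higher, 1 lower) and Kupffer cells (17 lower) among the lists of this comparison described so far.

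Tet1 KO YAP Tg livers were also set against controls. Of the 1985 genes at least 2-fold higher in YAP Tg than in control, 722 were higher and 104 lower in Tet1 KO YAP Tg than in control, with a median log2 fold change of 0.24. These genes were chosen against the same controls, which can push the count of higher genes and the median up. With genes chosen on some controls and measured against the others, the median was 0.149 or 0.242. Of all 13730 genes tested, 2769 were higher and 2585 lower than in control. Ankrd1 (0.646 ± 0.065 against 0.431 ± 0.298, adjusted p = 0.162) and Ctgf (22.4 ± 0.316 against 18.8 ± 5.68, adjusted p = 0.192) were not called, while Cyr61 was higher than in controls by 1.5 on the log2 scale (adjusted p = 3.01e-07), Gpc3 by 2.27 and Afp by 0.64 (adjusted p = 0.0104). Albumin (Alb) was lower, at 41340 ± 1020 against 99330 ± 8460, Cyp4a14 was at 0.337 against 259 ± 132, and Thrsp was higher, at 701 ± 13 against 139.

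In this comparison limma's camera called 10 of 32 lists at the preset correlation, and the lowest adjusted p of any list was 0.29 with an estimated correlation. Mitosis genes were higher in 17 of 24, 20 when adjusted over the list alone (median 0.63, adjusted p = 0.000153, and adjusted p = 0.519 with an estimated correlation). Fatty acid and triglyceride synthesis was higher in 12 and lower in 3 of 17 (median 0.45, adjusted p = 0.000493, and adjusted p = 0.516 with an estimated correlation), and fatty acid oxidation and ketogenesis lower in 11 of 18 (median -0.23, adjusted p = 0.000273, and adjusted p = 0.29 with an estimated correlation). Pericentral genes were lower in 10 of 14 (median -0.60, adjusted p = 0.00136, and adjusted p = 0.41 with an estimated correlation). YAP/TEAD targets, with 7 higher and 3 lower of 21 (8 and 3 adjusted over the list alone), were not called (median 0.30, adjusted p = 0.079), though they were with near-identical libraries added together (adjusted p = 0.00877). Between Tet1 KO YAP Tg and control, 2769 genes were higher and 2585 lower, 39% of those tested, with 260 and 257 at least 2-fold apart. With near-identical libraries added together 22 were higher and 16 lower. The call of Gpc3 held there (adjusted p = 0.0443), those of Cyr61 (adjusted p = 0.507), Afp (1), Alb (1) and Thrsp (0.509) ended, and Cyp4a14 was not tested. With libraries kept apart, edgeR called 1110 and 1090, and DESeq2's Wald test 1248 and 1300.

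Decitabine-treated Tet1 KO YAP Tg livers were compared with untreated ones, which asks how transcripts differ with decitabine in transgenic livers that per the labels lack Tet1. Decitabine libraries come in another unit than the rest, so for a single gene or list the drug and the processing cannot be told apart here. Ctgf was at 136 ± 34.8 with decitabine against 22.4 ± 0.316 without (log2 2.54, SE 0.215, adjusted p = 3.94e-07), Gpc3 at 448 ± 111 against 10.2 ± 0.483 (log2 5.36, SE 0.153, adjusted p = 1.15e-11) and Afp at 21.7 ± 4.23 against 2.91 ± 0.282. Ankrd1 was at 4.98 ± 4.82 against 0.646 ± 0.065 (adjusted p = 0.00384), Cyr61 at 31.3 ± 12.2 against 17.1 ± 1.05 (adjusted p = 0.0133), and Tet1 at 2.28 ± 1.07 against 0.931 ± 0.333 (adjusted p = 0.00943). Yap1 reads were higher, at 136 ± 44 against 51.1 ± 2.29 (adjusted p = 5.14e-05), Tet2 was at 32.5 ± 6.35 (adjusted p = 0.185) and Tet3 at 36.2 ± 17.4 (adjusted p = 0.0676). Cyp2e1 was lower, at 97.3 ± 54.3 against 4662 ± 116 (log2 -5.80, SE 0.361, adjusted p = 2.2e-08).

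Among the largest rises were those of Fgfbp1, Fam83b (186 ± 26.9 against 2.37), Vgll3, Spink3 (216 ± 72.8 against 4.39) and Gpc3. Fgfbp1 had 3 reads over the untreated group and was higher by a factor of 971 (95% counting interval 332 to 4710). The largest falls were again in Mup genes (Mup11, Mup2, Mup17, Mup15, Mup7 and Mup19), and Mup7 was at 0.163 ± 0.259 against 348 ± 15.2. The 340 genes with a named pseudogene had a median log2 fold change of -0.682, against 0.0745 for the 13600 others. The glycolytic gene Gapdh, chosen after its values were seen, was at 1.5 ± 0.180 against 524 ± 5.93 without the drug. A low level of such a gene, or of one with near-identical copies as in the Mup family, is therefore uncertain in the decitabine libraries.

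YAP/TEAD targets were higher in 12 and lower in 4 of 21, and the list was not called (median 0.76, adjusted p = 0.0892); Gadd45b went from 2.13 to 40.0 ± 9.08 and the receptor kinase Axl from 33.5 to 159.8 ± 55.2. Hippo components (9 of 19 higher, adjusted p = 0.0867), DNA methylation genes (8 higher and 3 lower of 16, 0.187) and cholangiocyte markers (7 and 3 of 14, 0.232) were not called. Uhrf1, which guides maintenance methylation, rose by 1.62 on the log2 scale, and Spp1 was at 1717 ± 913 against 314 ± 8.51. All 24 mitosis genes were higher (median 2.27, adjusted p = 1.92e-09, and adjusted p = 0.24 with an estimated correlation), with topoisomerase Top2a going from 16.1 to 105. DNA replication genes were higher in 21 of 23 (adjusted p = 2.61e-06, and adjusted p = 0.167 with an estimated correlation), and oncofetal genes in 9 of 13 (median 2.10, adjusted p = 0.00181, and adjusted p = 0.0534 with an estimated correlation), with Ly6d at 41.8 ± 14.4 against 1.44. The p53 targets were higher in 15 of 19 (adjusted p = 0.000521, and adjusted p = 0.0571 with an estimated correlation), including the kinase inhibitor gene Cdkn1a from 3.26 to 23.5.

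Metabolic lists were lower. Fatty acid oxidation and ketogenesis fell in 13 of 18 (median -0.71, adjusted p = 0.000317, 0.0488 with an estimated correlation), with Ppara going from 279.7 to 59.0. Cytochrome P450 genes were lower in 18 of 21 (adjusted p = 3.2e-07, and adjusted p = 0.106 with an estimated correlation), bile acid genes in 16 of 18 (adjusted p = 4.06e-07, and adjusted p = 0.0534 with an estimated correlation) and urea cycle and amino acid genes in 15 of 17 (adjusted p = 4.06e-07, and adjusted p = 0.24 with an estimated correlation). Cyp7b1, a hydroxylase of oxysterols, went from 196 to 6.67, and Ass1 from 1948 to 179. Cholesterol synthesis was lower in 18 of 20 (adjusted p = 4.06e-07, and adjusted p = 0.0534 with an estimated correlation), fatty acid and triglyceride synthesis in 15 of 17 (adjusted p = 4.06e-07, and adjusted p = 0.0534 with an estimated correlation) and pericentral genes in 12 of 14 (adjusted p = 4.06e-07, and adjusted p = 0.0534 with an estimated correlation). The sterol dehydrogenase Nsdhl fell by 3.36 on the log2 scale, Thrsp went from 701 to 13.3 and Slc1a2 from 98.5 to 1.04. Gluconeogenesis and glycogen genes were lower in 8 of 14 (adjusted p = 0.0345, and adjusted p = 0.24 with an estimated correlation), with Pck1 going from 2249 to 689; without decitabine library 3 the list was not called (adjusted p = 0.0563). Hepatocyte secreted proteins were lower in 10 and higher in 2 of 19 (adjusted p = 0.0446, and adjusted p = 0.563 with an estimated correlation), and Alb was among the higher ones at 102300 ± 9250 against 41340 ± 1020. This list was not called without Tet1 KO YAP Tg library 1 (adjusted p = 0.0556) or decitabine library 2 (adjusted p = 0.112).

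Immune markers were higher with decitabine. All 17 Kupffer cell and macrophage markers rose (median 2.60, adjusted p = 8.86e-09, 0.0488 with an estimated correlation), with Lyz2 at 531 ± 59.2 against 53.8 ± 3.57 and the macrophage protein gene Cd5l at 1251 ± 307 against 134. Lymphocyte markers were higher in 14 of 16 (adjusted p = 0.00414, and adjusted p = 0.24 with an estimated correlation), neutrophil markers in 11 of 13 (adjusted p = 0.00668, and adjusted p = 0.463 with an estimated correlation) and interferon response genes in 15 of 21 (adjusted p = 0.000892, and adjusted p = 0.424 with an estimated correlation). The antiviral synthetase Oas1a was at 21.2 ± 7.94 against 2.75. Erythroid genes were lower in 6 of 10 (adjusted p = 0.0297, and adjusted p = 0.424 with an estimated correlation), with Alas2 going from 113 to 17.4, and were not called without decitabine library 2 (adjusted p = 0.0803). Antigen presentation (10 of 16 higher, 3 lower, adjusted p = 0.0802) and fibroblast genes (5 of 19 lower, 0.324) were not called. Endothelial markers had 6 higher and 5 lower, a median of 0.03, a mean of -0.05 and a test pointing down (adjusted p = 0.925), with the receptor gene Kdr going from 106 to 34.9.

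Of 13940 genes, 4556 were higher and 3898 lower with decitabine (60.6%), 1927 and 1717 of them by at least 2-fold. With near-identical libraries added together 1768 were higher and 1798 lower, and the calls of Ankrd1 (adjusted p = 0.142), Tet1 (0.163), Cyr61 (0.288) and Alb (0.287) ended, as did those of the hepatocyte secreted protein (0.0759) and gluconeogenesis lists (0.0523); the call of Cyr61 also ended without decitabine library 3 (adjusted p = 0.0671). With decitabine reads doubled 1309 genes remained lower. Adjusted over the list alone, counts differed for bile acid genes (17 lower), fatty acid oxidation (2 higher, 13 lower) and interferon response (15 higher, 1 lower) among the lists of this comparison described so far.

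Against controls, decitabine-treated Tet1 KO YAP Tg livers had Gpc3 at 448 ± 111 and 1.72 ± 0.186 (log2 7.63, adjusted p = 2.6e-13) and Cyp2e1 at 97.3 ± 54.3 and 6892 ± 203 (log2 -6.36, adjusted p = 6.82e-09). They also had higher mitosis genes in all 24 (median 2.89, adjusted p = 5.75e-10, and adjusted p = 0.252 with an estimated correlation) and higher Kupffer cell and macrophage markers in all 17 (median 2.79, adjusted p = 4.93e-08, 0.0411 with an estimated correlation). YAP/TEAD targets were higher in 13 and lower in 5 of 21 (median 1.26, adjusted p = 0.0485, and adjusted p = 0.584 with an estimated correlation), and fatty acid oxidation lower in 15 of 18 (median -1.06, adjusted p = 6.82e-06, 0.0287 with an estimated correlation). In all, 5083 genes were higher and 4282 lower (67.2%), or 3226 and 2773 with near-identical libraries added together; with decitabine reads doubled 1449 remained lower.

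Against YAP Tg, the decitabine livers had Ctgf at 136 ± 34.8 and 148 ± 3.86 (adjusted p = 0.583), Afp at 21.7 ± 4.23 and 21.8 ± 0.886 (adjusted p = 0.925) and Cyp2e1 at 97.3 ± 54.3 and 83.3 ± 3.7 (adjusted p = 1), none of them called. Lower than in YAP Tg were Ankrd1 (log2 -3.96, adjusted p = 2.41e-05), Cyr61 (log2 -1.11, adjusted p = 0.00223) and H19 (log2 -4.32), and Yap1 was higher (log2 2.12). YAP/TEAD targets were not called (6 of 21 lower, median -0.06, adjusted p = 0.207). Interferon response genes were higher in 18 of 21 (median 0.85, adjusted p = 0.000404, and adjusted p = 0.545 with an estimated correlation), DNA replication genes in 14 (16 adjusted over the list alone) of 23 (adjusted p = 0.0106, and adjusted p = 0.545 with an estimated correlation), and oncofetal genes were lower in 8 of 13 (adjusted p = 0.0389, and adjusted p = 0.517 with an estimated correlation). In all, 3537 genes were higher and 2714 lower (44.8%), or 150 and 691 with near-identical libraries added together, where the call of Cyr61 ended (adjusted p = 0.189); with decitabine reads doubled 732 remained lower.

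**Figure D2:**
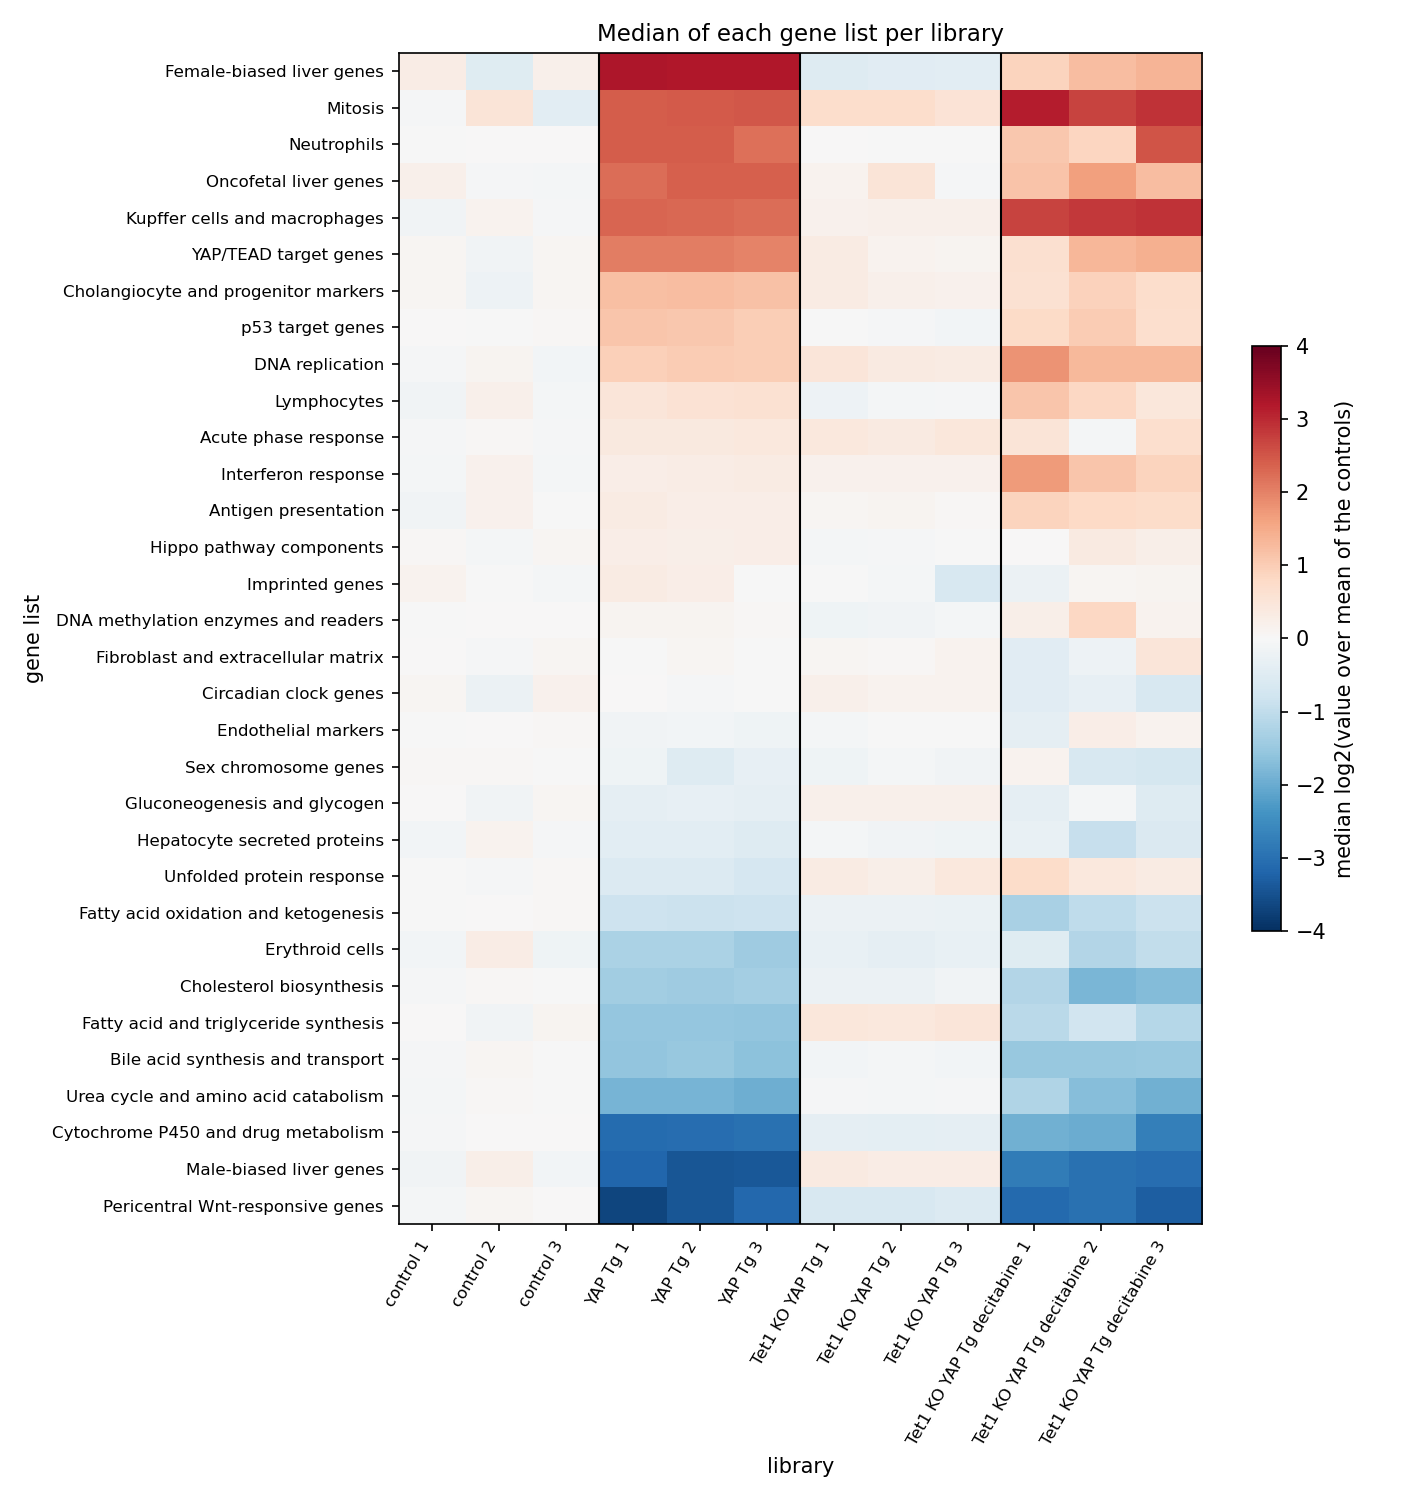
Each row is a gene list and each column 1 of the 12 libraries; colour is the median over the list's genes of log2(value over the mean of the controls). Lists are sorted by their value in YAP Tg; Tet1 KO YAP Tg columns lie near 0 for most lists, and decitabine columns take the colours of YAP Tg in many.

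The question whether the genes changed by YAP are those changed by loss of Tet1 and by decitabine was put to the overlaps. Of 4951 genes higher in YAP Tg than in control, 3914 (79.1%) were lower in Tet1 KO YAP Tg than in YAP Tg, where independent lists would share 1682. Both comparisons use the YAP Tg libraries, so part of the excess may come from these shared libraries. In 50 simulations with no group difference no gene was shared, but hardly any gene can be called there, so they do not show how much shared noise adds. Of the genes lower in YAP Tg, 3727 (78.8%) were higher without Tet1. The comparisons of YAP Tg with control and of decitabine with its untreated group share no library: 3273 of 4949 genes (66.1%) higher in the first were higher in the second (independent lists would share 1586, odds ratio 13.3), and 2618 (55.4%) of those lower were lower (1343, odds ratio 7.48). Both groups of the first comparison have the same unit, so a difference in processing predicts no such sharing. These values argue against processing as the source of the shared direction, but not for single genes or lists.

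All 3 calls, higher with YAP, lower without Tet1 and higher with decitabine, were found in 2894 of 13722 genes, against 558.7 for independent lists, and in 1151 with each change at least 2-fold. These comparisons share YAP Tg and Tet1 KO YAP Tg libraries, so part of the excess may come from that; simulations with no group difference gave 0 genes, with the same limit as above. Among those with the largest change by YAP were Fgfbp1, Gpc3, Fam83b, Spink3, Psca, the surfactant protein gene Sftpd and the class I gene H2-Q1. Psca rose little with decitabine, with 0.071, 0.727 and 6.93 normalised reads in the 3 libraries against 82.9 in YAP Tg, so its rise rests mostly on 1 library. H2-Q1 went from 4.82 in controls to 408 ± 10.5 in YAP Tg, 121 in Tet1 KO YAP Tg and 389 ± 100 with decitabine, and Sftpd from 0.319 to 91.7, 1.74 and 74.5 ± 54.9. The reverse pattern, lower, higher and lower, was found in 2339 genes, and in 621 at 2-fold. The near-identical libraries matter here: with these added together the overlaps held 705 genes (higher with YAP, lower without Tet1), 1093 (higher with YAP and with decitabine) and 603 (all 3 calls).

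**Figure D3:**
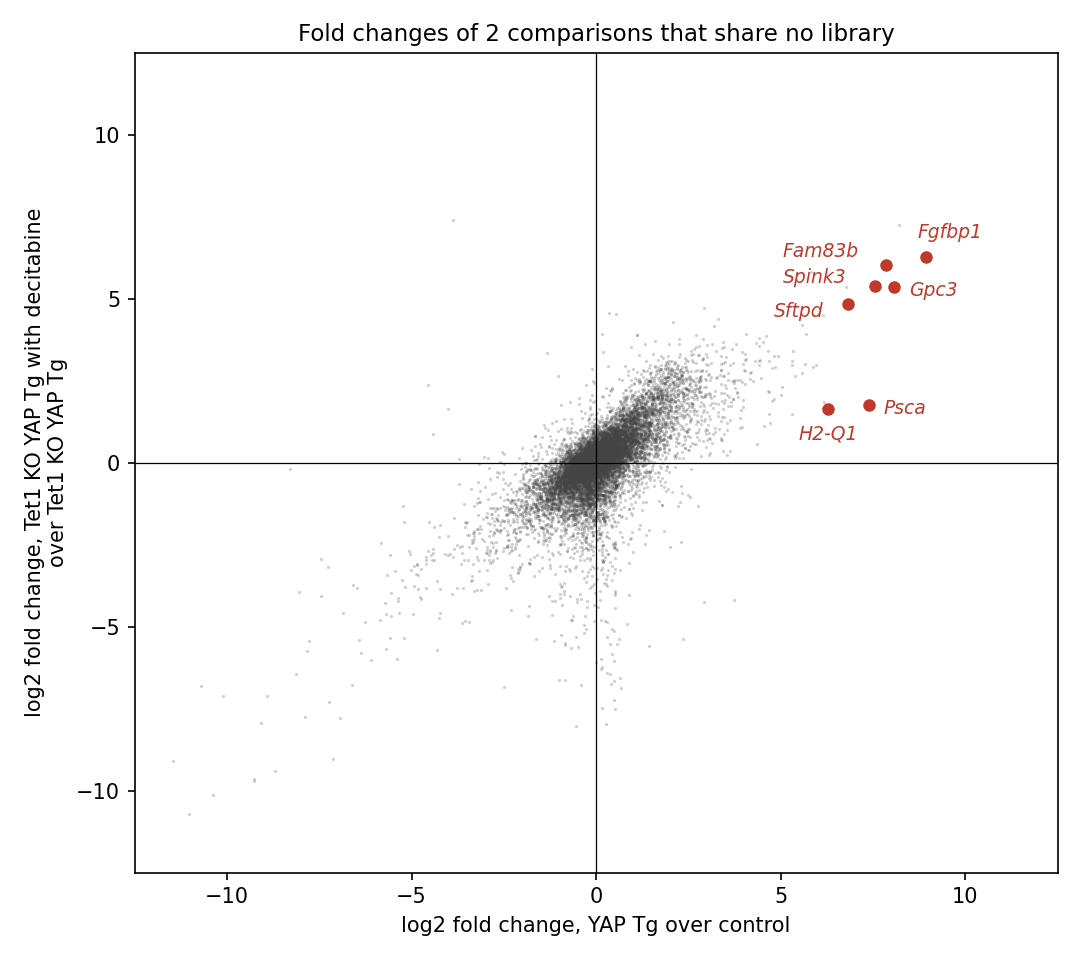
Each point is a gene; the horizontal axis is its log2 fold change in YAP Tg over control and the vertical axis that in decitabine-treated over untreated Tet1 KO YAP Tg, with 7 genes of the 3-call pattern named in red. Pearson's correlation across genes is 0.71, and the named genes lie in the upper right.

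Over the 1985 genes at least 2-fold higher in YAP Tg than in control, the median log2 fold change over control was 1.59 in YAP Tg, 0.24 in Tet1 KO YAP Tg and 1.67 with decitabine. Over the 1288 genes at least 2-fold lower it was -1.5, -0.29 and -1.41. These genes were chosen by the first of these comparisons, so its own medians are partly set by the choice, and the other medians are over the same controls. Measured against controls not used to choose the genes, the median of the lowered genes in Tet1 KO YAP Tg was -0.179 (1382 genes) or -0.174 (1199 genes), and that of the raised ones 0.149 or 0.242. Across all genes, the fold changes of YAP Tg over control had a Pearson correlation of 0.71 (Spearman 0.702) with those of decitabine over its untreated group, which share no library, and of -0.907 with those of Tet1 KO YAP Tg over YAP Tg, which share the YAP Tg libraries. For that pair simulations with no group difference gave a correlation of -0.263, and the covariance was -1.08 against -0.00478 simulated. Genes are not independent replicates, and these correlations carry no p-value. A test for any difference among the 4 groups called 11154 of 13940 genes, and 5024 with near-identical libraries added together.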

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

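The correlations with gene length were tests chosen after the values were seen. The table also holds fold changes that the authors computed, which the comparisons here do not use. In the column for decitabine-treated over untreated Tet1 KO YAP Tg, the deposited log2 fold change had a Spearman correlation of -0.572 with recovered gene length across 13940 genes, so longer genes had lower fold changes, and in the column for YAP Tg over decitabine, where the decitabine libraries are the base, it was 0.725. In the columns among control, YAP Tg and Tet1 KO YAP Tg it lay between -0.0847 and 0.00108, and in fold changes computed here from recovered reads it was 0.0963 for decitabine over its untreated group. This result stands here because it is a signal in columns outside the main measurement, beyond the level in the columns without decitabine.

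The deposited and the computed fold changes ranked genes alike without decitabine (Spearman 0.994 for YAP Tg over control, 0.994 for Tet1 KO YAP Tg over YAP Tg and 0.988 for Tet1 KO YAP Tg over control) and less so with it (0.68 for decitabine over its untreated group). The deposited false discovery rates called 3551 genes higher and 3733 lower with decitabine, against 4556 and 3898 here. Given the length trend, the deposited calls may mix units, so these counts are not like for like. Genes are not independent replicates, and these correlations carry no p-value.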

How the results depend on the processing

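The summed libraries, the changed pseudocount, edgeR on recovered reads, the decitabine alternatives, the fits with all 12 libraries and the omission of genes with a named pseudogene were tests chosen after the data were seen. Depth and number limit these data, with 3 libraries per group, and the near-identical libraries leave open how many independent samples stand behind each group. In simulated data a 1.5-fold change was recovered in 21.6% of genes for YAP Tg over control. That simulation used the spread of all 12 libraries, decitabine included, and need not hold for the narrower spread of the real groups. No result that was called, in the main fit or under an alternative, turned its direction between them. Some that were called in neither did, such as the acute phase list in YAP Tg over control and the acute phase, imprinted and unfolded protein lists in decitabine over its untreated group, all with near-identical libraries added together, and Tet3 in YAP Tg over control (-0.0669 without control 2, against 0.0496). Where a count below moved, the cause was not tested unless a clause says otherwise.

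With near-identical libraries added together, YAP Tg and Tet1 KO YAP Tg have 1 library each and the counts fell. Higher and lower genes were 1642 and 987 for YAP Tg over control, 527 and 744 for Tet1 KO YAP Tg over YAP Tg (all of them at least 2-fold, 527 and 744), 1768 and 1798 for decitabine over its untreated group, 22 and 16 for Tet1 KO YAP Tg over control, 3226 and 2773 for decitabine over control, and 150 and 691 for decitabine over YAP Tg. The test among the 4 groups gave 5024 genes, and the overlaps 705, 1093 and 603. With a 2-fold limit added, which by its construction calls fewer, they were 1985 and 1288, 1116 and 1714, and 1927 and 1717 in the first 3 comparisons. A pseudocount of 2, which shrinks fold changes of low genes, left 1294 genes at least 2-fold higher in YAP Tg and 1109 at least 2-fold lower without Tet1. Doubling the decitabine reads, which makes the test for lower genes stricter, left 1309 lower than in the untreated group (692 at least 2-fold), 1449 lower than in control and 732 lower than in YAP Tg. Decitabine TPM as deposited gave 2969 and 3265 genes at least 2-fold higher and lower than in the untreated group, and 5692 lower than in YAP Tg. For Tet1 KO YAP Tg over control, DESeq2's Wald test called 1248 and 1300 genes, edgeR 1110 and 1090, and limma with all 12 libraries 1314 and 1146. An estimated correlation left 10, 8 and 2 lists in the first 3 comparisons.

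With each library left out in turn, no count moved by over 1.5 times. YAP Tg over control gave 4287 to 5246 higher and 4393 to 5046 lower genes, Tet1 KO YAP Tg over YAP Tg 4187 to 4305 and 4009 to 4369, decitabine over its untreated group 4034 to 4954 and 3393 to 4190, and Tet1 KO YAP Tg over control 2069 to 3902 and 1938 to 3586. The genes with all 3 calls were 2471 to 3068, and the lists called 17 to 21, 19 to 21 and 19 to 23. Where an arm keeps 2 libraries, its spread is assumed to be that of the other groups. Of the results for named genes, 1907 stayed on their side of the threshold, called or not, 3 gained a call and 10 lost it; for lists 548 stayed, 11 gained and 11 lost it. Across the other alternatives, 58 results for named genes lost their call with near-identical libraries added together (267 stayed), 5 with edgeR, 3 with DESeq2's Wald test, 4 with all 12 libraries, 3 with only the 6 libraries compared, 1 with no filter and 1 with the block, and none with DESeq2 size factors, the stricter filter or the other pseudocounts. Of results for lists, 41 lost their call with an estimated correlation (55 stayed) and at most 3 under any other of these alternatives.

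The replicate number as a block gave 4933 and 4720 genes for YAP Tg over control, 4594 and 4652 for Tet1 KO YAP Tg over YAP Tg and 4441 and 3835 for decitabine over its untreated group, and of the named genes Uty lost its call (adjusted p = 0.0659). The numbers do not pair the libraries throughout: of 18 pairs with the same number in different groups, the correlation of residuals was over 0.1 in 5 (range -0.187 to 0.441), so unpaired values are given. Libraries numbered 3 did go together outside the decitabine group. The correlation was 0.257 for control with YAP Tg, 0.441 for control with Tet1 KO YAP Tg and 0.248 for YAP Tg with Tet1 KO YAP Tg. The highest with other numbers was -0.13, -0.232 and -0.09. DESeq2 size factors moved the median log2 fold change of all genes for decitabine over its untreated group from 0.068 to 0.00556. Without genes that have a named pseudogene 4483 genes were higher and 3701 lower in that comparison. The test among all 4 groups was not run with only 6 libraries, since it needs them all.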

Other observations

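Of the tests in this part, those on pseudogenes, on female animals and on transgene activity were chosen after the result was seen; the neuron test and the splits were fixed earlier.

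Sex-biased liver genes, which respond to the pattern of growth hormone release, were among the most changed. All male-biased genes but 2 were lower in YAP Tg than in control (13 of 15, median log2 -3.33, adjusted p = 1.29e-08, and adjusted p = 0.137 with an estimated correlation), all 15 were higher without Tet1 (median 4.31, adjusted p = 1.24e-10, and adjusted p = 0.0867 with an estimated correlation), and 14 were lower with decitabine than without (median -3.07, adjusted p = 8.86e-09, and adjusted p = 0.0534 with an estimated correlation). Hsd3b5, a steroid dehydrogenase of male liver, was at 270.5 ± 77.5 in controls, 0.0471 in YAP Tg, 152 in Tet1 KO YAP Tg and 0.826 with decitabine. Mup1 had no read in YAP Tg and was at least 4050-fold lower there than in controls. Female-biased genes were higher in 6 of 8 in YAP Tg, where the list was not called (adjusted p = 0.0544) unless near-identical libraries were added together (0.019) or under some other alternatives, lower in 7 without Tet1 (adjusted p = 0.00142, and adjusted p = 0.142 with an estimated correlation) and higher in 5 with decitabine (adjusted p = 0.0173, and adjusted p = 0.167 with an estimated correlation). The hydroxyacid oxidase gene Hao2 was at 0.281 in controls, 18.5 in YAP Tg, 0.0476 in Tet1 KO YAP Tg and 11.3 ± 12.7 with decitabine, and the transcription factor gene Cux2 rose from 0.566 to 13.6 with YAP. Sex chromosome genes were not called as a list in these 3 comparisons (adjusted p = 0.193, 0.269 and 0.503); 3 of 5 were lower with YAP, 2 higher without Tet1 and 1 lower with decitabine, and the helicase gene Ddx3y had log2 fold changes of -0.49 and 0.33 in the first and second, neither called with near-identical libraries added together (adjusted p = 0.49 and 0.752).

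Other groups split within themselves. Imprinted genes were not called in the 3 comparisons (adjusted p = 0.25, 0.0659 and 0.721, with 8, 2 and 8 of 17 higher and 3, 9 and 6 lower); the zinc finger gene Peg3 went from 12.51 in controls to 102 in YAP Tg and 5.80 without Tet1. Acute phase genes were 10 higher and 8 lower with YAP, with a median of 0.42, a mean of -0.15 and a test pointing up (adjusted p = 0.885). Without Tet1 they were 8 higher and 10 lower, with a median of -0.49, a mean of 0.35 and a test pointing down (adjusted p = 0.846). With decitabine they were 9 higher and 7 lower, with a median of 0.29, a mean of -0.22 and a test pointing down (adjusted p = 0.856). The orosomucoid Orm1 fell from 909 to 4.72 with YAP, while the metallothionein Mt2 was at 3.05 without Tet1 against 75.7 with it. Unfolded protein response genes were lower in 10 and higher in 3 of 16 with YAP (adjusted p = 0.0414, and adjusted p = 0.146 with an estimated correlation), a call that ended without YAP Tg library 1 (adjusted p = 0.0510) or 3 (adjusted p = 0.0507) and with near-identical libraries added together (adjusted p = 0.0539). They were higher in 11 and lower in 4 without Tet1 (adjusted p = 0.0131, and adjusted p = 0.0867 with an estimated correlation). With decitabine the list was not called, with 3 higher and 6 lower. It had a median of -0.04, a mean of 0.29 and a test pointing down (adjusted p = 0.856). Asparagine synthetase (Asns) rose from 0.449 to 14.0 there. Its level was 7.88 in controls and 8.81 in YAP Tg, so the untreated Tet1 KO YAP Tg livers were the low group. Circadian clock genes were not called with YAP (median 0.02, mean 0.15, test pointing down, adjusted p = 0.91; 5 higher, 5 lower) or without Tet1 (8 higher, 2 lower, adjusted p = 0.12). With decitabine 12 of 16 were lower and 3 higher (adjusted p = 0.0118, and adjusted p = 0.414 with an estimated correlation). The clock output gene Dbp went from 20.4 to 0.615 there. Dbp was at 3.44 ± 1.89 in controls and 26.4 ± 1.57 in YAP Tg, so its untreated level was already above control (log2 2.56). Adjusted over the list alone, counts differed for circadian (7 higher) and imprinted genes (3 higher) without Tet1, and for female-biased (6 higher) and sex chromosome genes (0 higher and 0 lower) with decitabine.

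The first pattern is a set of 201 genes at least 4-fold lower in the decitabine libraries than in each of the other groups. Of these, 75 (37.3%) have a named pseudogene, against 340 of 13940 genes tested (2.44%; odds ratio 30.2, Fisher's exact test, two-sided p = 4.74e-70), and examples chosen after their values were seen are Gapdh and Ppia, at 1.5 and 1.55 normalised reads with decitabine against 524 and 503 without. A candidate explanation is that reads matching several places of the genome were left out when the decitabine libraries were counted. A fall caused by decitabine itself predicts no such enrichment, and the lower 95% bound of the odds ratio, 21.8, argues against it as the cause for the genes with a named pseudogene. For the other 126 genes the drug and the processing cannot be told apart, because no library of another group was processed as these were. The recovery of reads may add to such falls. In simulated data 0.6659% of genes with a mean of at least 10 reads came back too small by a whole factor above 3. Such an error lowers a gene in all 3 decitabine libraries, and how many of the 201 genes it made was not tested.

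The second pattern is that Xist, the RNA of the inactive X chromosome, was at 3.73 to 15.3 normalised reads in 5 libraries (controls 1 and 2, YAP Tg 1, Tet1 KO YAP Tg 2 and 3) and at 0.0894 to 0.248 in the other 7, at least 41.7 times the lowest of its group in each of the 5. Female animals would lower the Y-linked genes, but in these 5 libraries their sum was at least 0.924 of the highest in the group, which argues against that. RNA of a neural sample mixed into the libraries might raise neuronal genes too, and a list of 32 such genes was at least 2 times its group's lowest in 2 of the 5 (control 2, with a sum of 110 against 54.5 in control 3, and Tet1 KO YAP Tg 2), yet also 2.29 times in Tet1 KO YAP Tg 1, which lacks Xist. Mixing therefore stays open, and no biological explanation other than female animals was tested. The imprinted neuronal transcripts Nnat and Meg3 were low in control 3 and in all decitabine libraries, which lack Xist, but also in Tet1 KO YAP Tg 3 (1.49 and 0.267), which has it, so they do not follow Xist in every library. They fell with decitabine (log2 -3.65 and -2.63), and the fall of Meg3 was not called without Tet1 KO YAP Tg library 1 (adjusted p = 0.0695) or 2 (adjusted p = 0.0755).

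The third pattern is that Tet1 KO YAP Tg livers were close to control. With genes at least 2-fold higher in YAP Tg chosen on controls 1 and 3 and measured against control 2, their median log2 fold change in Tet1 KO YAP Tg was 0.149 over 2068 genes (0.186, 0.156 and 0.132 in the 3 libraries), against 1.48 in YAP Tg, and with the roles of the controls exchanged it was 0.242 over 1938 genes. A transgene that was not active in these livers could give the same closeness as a requirement for TET1, and these remain open together. Ajuba (log2 2.34), Gpc3 (2.27) and Cyr61 (1.5) were above control, and the YAP/TEAD target list, not called there (adjusted p = 0.079), was called higher with near-identical libraries added together (adjusted p = 0.00877). That this list must also be called was added after 0.149, which passes the bound of 0.1 first set, had been seen. Neither value settles the question, because a loss of TET1 without the transgene was not among the groups, and the deletion alone could raise these genes too. A lower transgene expression could do so too: Yap1 reads were higher in Tet1 KO YAP Tg than in YAP Tg (log2 0.767), but the labels do not say which species' YAP the transgene carries, so these reads need not come from it.

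Other splits of the libraries were fitted in the same way. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. In YAP Tg and control the real split gave 9682 genes and the highest other 0, and 1 of the 10 gave as many; limma gave 40 to 637 genes at an unadjusted p under 0.05 in the other splits. In the other comparisons 1 of 10 gave as many too. The real and the highest other counts were 9251 and 0 for Tet1 KO YAP Tg and YAP Tg (25 to 86 unadjusted in the others), 8454 and 0 for decitabine and its untreated group (176 to 1123), 5354 and 0 for Tet1 KO YAP Tg and control (173 to 2089), 9365 and 1 for decitabine and control (216 to 1900), and 6251 and 0 for decitabine and YAP Tg (497 to 1119). Each other split mixes both groups, and the difference between them widens its spread. Of lists called, the real split gave 19 in YAP Tg and control, with 19 as the highest other (2 of 10 as many), 21 and 20 for Tet1 KO YAP Tg and YAP Tg, and 21 and 19 for decitabine and its untreated group. Of 100 random splits into groups of 3, the real one included, 1 gave as many genes as the real one for the test among all groups (11154, highest other 1277, which kept the decitabine libraries together), for genes higher with YAP and lower without Tet1 (3914, highest other 3580, in splits of the 9 libraries without decitabine), for genes higher with YAP and with decitabine (3273, highest other 0) and for all 3 calls (2894, highest other 0); apart from the second, these split all 12 libraries. So no other split drawn gave as many for these 4. Here too a split that mixes groups takes the difference between them into its spread, which lowers its count. These splits therefore cannot exclude chance in how the libraries were grouped. Chance among animals is not excluded either, since the near-identical libraries may not be separate animals. The split with 3580 kept the YAP Tg libraries together and mixed controls with Tet1 KO YAP Tg, so that overlap rests on YAP Tg standing apart from both.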
